A study of Arabidopsis thaliana with 3 samples.

How the data were processed

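RNA of whole wild-type Col-0 seedlings was measured in 3 libraries, which the labels' titles number as replicates 1 to 3 of 1 group. Each title also ends in (2), which the labels do not explain. Per the labels' protocols, total RNA was depleted of ribosomal RNA, strand-specific libraries were prepared and sequenced on an Illumina HiSeq instrument. The deposited files hold 1 value per transcript for 36172 transcripts in each library. The unit is not given in the file headers. It was taken to be FPKM made by the authors, because the submitters' processing notes name Cufflinks 2.1.1, and because the values are not whole, not negative and sum to a different total in each library. The same notes name TopHat2 2.0.9 and the genome build TAIR10, with no role or order. The annotation used, filters and any scaling between libraries are not given in the sources used here.

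Of the transcripts, 35337 carry the identifier of a TAIR locus and were summed per locus, giving 27374 genes (27164 nuclear, 88 chloroplast and 122 mitochondrial). The other 835 (563 with identifiers that start with TCONS and 272 with another prefix) have no locus and entered no comparison of genes. They do count in the summed FPKM and so in every share of it. Gene names, biotypes and lengths came from the RefSeq annotation of TAIR10.1, which differs from the authors' build in name, and 26702 of the 27374 identifiers matched its gene table, 26693 of them nuclear protein-coding genes. The 672 unmatched ones include 462 nuclear genes. Every coordinate given is from TAIR10.1. FPKM depends on how reads were divided between overlapping or near-identical genes, so values of close paralogs are uncertain. It is also unstable for transcripts shorter than the sequenced fragments, whose effective length is very small, and a few abundant organelle transcripts change the share that is left for other genes.

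Read depth is not stated. In genes with 1 transcript and low values, FPKM clustered at steps that fit denominators of about 20.3, 19.5 and 20.9 megafragments in libraries 1, 2 and 3. However, 39.0%, 37.5% and 39.6% of those values were whole multiples of a step within 0.05, where chance gives 10%, so whole reads were not recovered and no count test was made. Between libraries, genes with 10 to 100 estimated fragments varied by a median of 1.39 to 1.52 times, and those with 100 to 1000 by 1.66 to 1.97 times, what counting error gives in a chi-square statistic. Error of the estimated fragments may add to this excess, so it does not show that the libraries are separate replicates. The 3 libraries were treated as distinct because the labels number them so. Values listed as 0 can be failed estimates and were reported as listed.

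The analysis was fixed before the data were examined, except where the closing section says otherwise. It comprised 24 gene lists with 358 genes, of which 353 were in the files, and 35 list members whose listed symbol is not the one in the gene table are given with their locus where named. For each list, the median percentile rank of mean log2(FPKM + 1) among nuclear protein-coding genes was compared with 10000 random lists of the same size, and a list stood apart outside the central 95%. Members of gene families were compared with limma (intercept model, empirical Bayes with trend, fitted over genes with a mean of at least 1 FPKM) on the log2 ratio to a reference member, with Benjamini-Hochberg adjustment over 21 pairs and a threshold of 0.05. Folds on this scale understate differences of low genes. Mean log2 values of list pairs were compared with exact two-sided sign-flip permutation tests. For each library, the median deviation of a list from the other libraries was compared with 10000 random lists matched on expression in 20 bins, with the central 99% as the bound. Genes that differed were those whose highest and lowest library were more than 1 apart on the log2 scale.

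Genes named in the text were the 20 nuclear protein-coding genes with the highest mean, the 10 genes with the largest SD of log2(FPKM + 1) at a mean of at least 10, all family members, and for each list the 2 highest members, the lowest and the one with the largest SD, with further members of small lists. Organelle genes and transcripts without a locus were chosen after their values were seen, as the highest ones. A lowest member tied with others at 0 was chosen from these.

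The family and deviation tests were tested on simulated data with the level of 17868 genes. Each gene varied independently there, with the median spread of genes of similar level. For the family comparison, pairs 0.5 apart were called in 100% and pairs 0.25 apart in 84%, and 8.5% of equal pairs had an unadjusted p below 0.05, so the test is somewhat liberal. A fit with the variances of both genes gave 3.5% and was added as an alternative. Lists raised by 0.3 in 1 library were placed above the central 99% in 100% of cases, and 0.33% of unchanged lists were placed outside it. These shares do not describe lists whose genes move together. For the level test, run on measured ranks of 26693 genes, lists drawn from the most abundant 25% of genes were placed above in 100%. This was fixed in advance, since the upper bound for such lists of 12 genes was a rank of 74.8, so it says nothing on power. Of random lists, drawn from the same ranks as the bound, 3.3% were placed outside. Alternatives left out each replicate, scaled libraries by median-of-ratios size factors (1.01, 0.984 and 1.01), used a pseudocount of 0.1, no filter, lower detection limits, other backgrounds, no variance trend or medians over list members. Second copies of transcripts were searched with BLAST 2.17.0. The cover given is that of the longest single match, which introns can break, so it is a minimum. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, pysam 0.24.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Trans-acting siRNA loci of the non-coding list were not analysed here, because their identifiers were not among those listed.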

Results

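The data consisted of 3 RNA-seq libraries from whole seedlings of Arabidopsis thaliana Col-0, the reference accession of this plant. The seedlings were wild type, 9 days old, and had grown on plates at 23 °C with 16 h of light and 8 h of darkness. Total RNA had been depleted of ribosomal RNA and made into strand-specific libraries, so that transcripts without a poly(A) tail were kept. The 3 libraries form 1 group. The series title names adenine methylation of DNA, and its RNA part, as analysed here, holds no mutant or treated sample. The comparisons therefore set genes against each other within the seedlings and the 3 libraries against each other. The labels do not say whether the libraries came from separate plant cultures, so every SD and p-value below measures the spread between these libraries. Values are FPKM, summed over the transcripts of a gene. Over all 36172 transcripts, with the 835 that have no locus, they added up to 2064650, 2000110 and 1957870 in libraries 1, 2 and 3. Of 27374 listed genes, 17369 (63.5%) had at least 1 FPKM in every library, and 4506 were listed at 0 in all of them.

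Genes of photosynthesis led the nuclear transcriptome. Of the 20 most abundant nuclear protein-coding genes, 14 belonged to the list of light reaction genes and 2 to the Calvin cycle list. CAB1 (AT1G29930), which encodes a chlorophyll a/b-binding protein of the photosystem II antenna, had 14284 ± 737 FPKM (SD, n = 3), and LHB1B2 (AT2G34420), of the same antenna family, had 11033 ± 515. PSBR, a photosystem II subunit, had 7124 ± 272 FPKM. The antenna genes LHCA3, LHCB5, LHCA4, LHCB3, LHB1B1, LHCA1 and LHCA2 lay between 4030 and 2826 FPKM, and PSBO1, PSAG and PSAO, which encode further photosystem subunits, between 2802 and 2571. CAB3 had 4190 ± 247 FPKM. Second genomic copies at 90% identity or more covered 99.8% of the transcript of CAB3, 76.6% of that of LHB1B2, 61.2% of that of LHB1B1 and 30.5% of that of LHCA2, so the split of reads within these families is uncertain.

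The other 4 of the 20 genes were in none of the lists. AT2G35750, annotated as an uncharacterized protein, had the highest value, 18681 ± 1260 FPKM. In TAIR10.1 it lies on chromosome 2, from 15029829 to 15030348 on the minus strand, and its exon holds 2 annotated snoRNA genes on the same strand. AT2G07671, annotated as an ATP synthase subunit C family protein, had 7385 ± 309 FPKM. In TAIR10.1 its single-exon transcript spans 3251566 to 3252341 of chromosome 2 and is 100% identical, over 100% of its length, to a stretch of the mitochondrial genome that holds atp9. AT2G31141, an uncharacterized protein, had 4088 ± 585 FPKM, and AT2G45180, of the lipid-transfer protein superfamily, had 3109 ± 65.0.

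**Figure D1:**
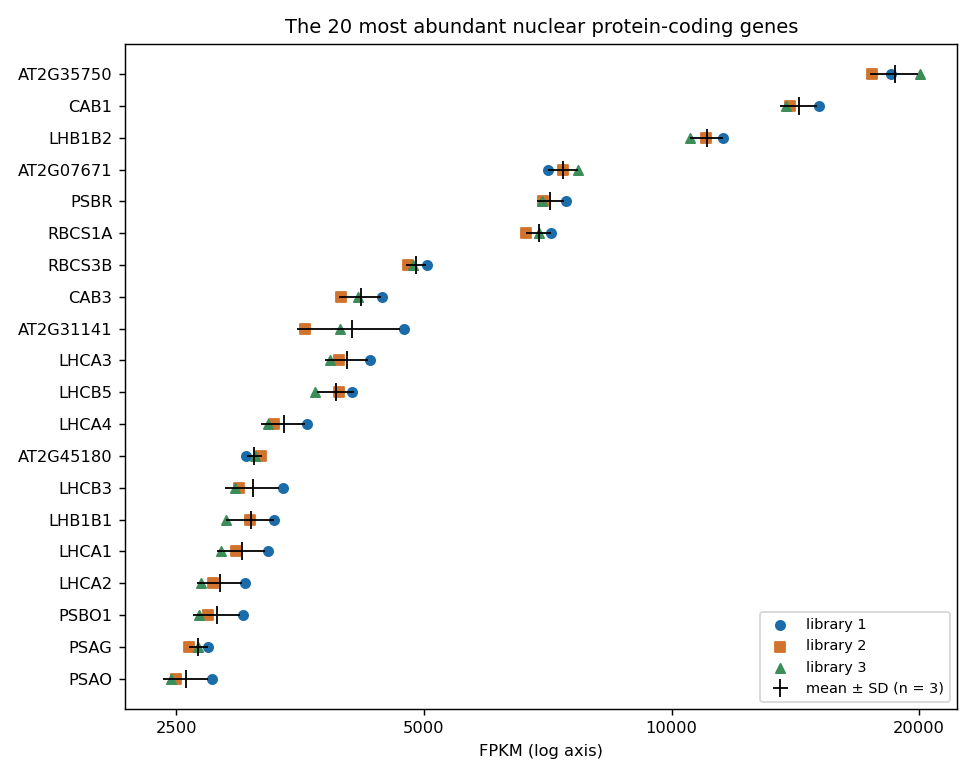
FPKM of the 20 most abundant nuclear protein-coding genes on a log axis, with 1 symbol per library and the mean ± SD over 3 libraries as a line. Values run from 18681 FPKM for AT2G35750 to 2571 for PSAO, and the libraries lie close together for each gene.

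All 3 photosynthesis lists lay above the central 95% of random gene lists in expression rank. The 39 nuclear-encoded light reaction genes had a median of 1815 FPKM and a median percentile rank of 99.9 among nuclear protein-coding genes. All 39 exceeded 100 FPKM, and the lowest was PETE1, a plastocyanin gene, at 189 ± 11.1. LHCB2.3 varied most between libraries, with an SD of 0.15 on the log2 scale. The 17 Calvin cycle genes had a median of 549 FPKM and a median rank of 99.6, all above 100 FPKM. RBCS1A, a small subunit of Rubisco, was highest at 6896 ± 241, RBCS3B followed at 4890 ± 136, and the triose phosphate isomerase gene TPI (AT2G21170, TIM in the gene table) was lowest at 191 ± 6.43. The Calvin cycle member with the largest SD was CP12-2, a regulator of the cycle, at 299 ± 27.5 FPKM. The mean log2(FPKM + 1) of light reaction genes exceeded that of Calvin cycle genes by 1.35 ± 0.01 (SD, n = 3), a ratio of 2.55, in each of the 3 libraries. The exact two-sided sign-flip permutation test gave p = 0.25 for this and every other contrast of lists below, the smallest value that 3 libraries allow, so none of these contrasts can pass a threshold of 0.05.

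The 12 chlorophyll synthesis genes had a median of 144 FPKM and a median rank of 98.0. CRD1, a cyclase of the pathway, led with 783 ± 44.4 FPKM. The protochlorophyllide oxidoreductases differed widely: PORB had 613 ± 26.3, PORC (AT1G03630) 99.6 ± 4.43 and PORA, the form abundant in dark-grown seedlings, 1.11 ± 0.439. On the log2(FPKM + 1) scale the difference from PORB was -8.20 for PORA (SE 0.13) and -2.61 for PORC (SE 0.047), negative in 3 of 3 libraries each, with limma adjusted p-values of 6.9e-13 and 1.5e-12. PORA also had the largest SD of this list, and without replicate 2 its mean fell under the 1 FPKM filter of the test. Among the Rubisco small subunits, the log2 difference from RBCS1A was -0.50 for RBCS3B, -1.99 for RBCS2B and -2.52 for RBCS1B, with limma adjusted p-values of at most 6.3e-05. The longest single match to a second copy, at 90% identity or more, covered 19.2% of the transcript of the reference RBCS1A. It covered 13.8%, 28.2% and 21.9% of those of RBCS1B, RBCS2B and RBCS3B. Introns can break such matches, so the shared part may be larger, and part of the reads of these genes cannot be assigned with certainty.

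Genes of cytosolic ribosomal proteins and of histones also ranked high. The 14 cytosolic ribosomal protein genes had a median of 170 FPKM and a median rank of 98.3, from RPL3A (AT1G43170, RP1 in the table) at 506 ± 25.8 and RPS6B (AT5G10360, EMB3010 in the table) at 276 ± 19.6 down to RPS5B at 88.5 ± 10.4. The largest SD among them was that of RPL4D (AT5G02870), at 171 ± 23.0 FPKM. Light reaction genes exceeded them by 3.25 ± 0.14 in mean log2(FPKM + 1). The 18 reference (housekeeping) genes had a median of 192 FPKM and a median rank of 98.6. UBQ10 led with 1048 ± 73.3, the translation elongation factor entered as EF1A4 (AT5G60390) had 817 ± 95.3 and the largest SD, and SAND (AT2G28390) was lowest at 10.2 ± 0.206. Of the actins, ACT2 had 362 ± 6.95 FPKM, and the log2 difference from it was -0.49 for ACT7 and -0.98 for ACT8, with limma adjusted p-values of 1.0e-05 and 1.3e-07. Second matches at 90% identity or more covered 18.9%, 3.53% and 34.3% of the transcripts of ACT2, ACT7 and ACT8. They covered 63.8% of that of UBQ10 and 48.7% of that of EF1A4, so the split of reads is uncertain for these genes too. The 19 genes for core histones and variants had a median of 47.8 FPKM and a median rank of 93.2. The genes entered as HTR5 (AT4G40040) and HTR4 (AT4G40030), which encode histone H3.3, had 392 ± 16.2 and 276 ± 4.95 FPKM, the H2A.Z gene HTA8 was lowest at 7.80 ± 0.731, and HIS4 varied most, at 21.9 ± 3.59. The 19 cell cycle and DNA replication genes lay within the range of random lists, with a median of 5.91 FPKM and a median rank of 57.6. The cytokinesis syntaxin KN (AT1G08560, SYP111 in the table) had 23.4 ± 1.35 FPKM, the D-type cyclin CYCD3;1 17.7 ± 0.543, CYCA2;1 0.459 ± 0.141, and CDKB2;2, with the largest SD, 4.71 ± 0.845.

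**Figure D2:**
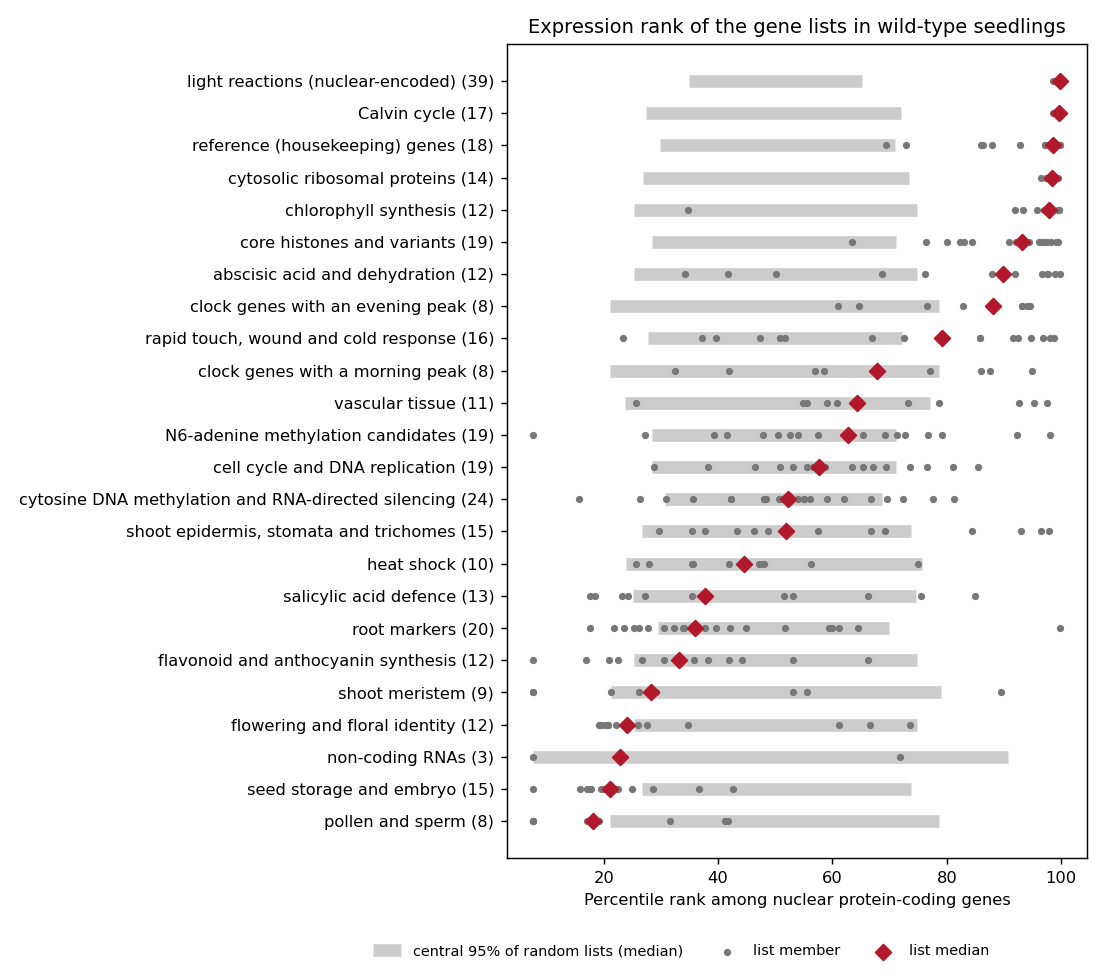
Percentile rank of each list member (grey points) and of the list median (red diamonds) among nuclear protein-coding genes, with the number of members in brackets and the central 95% of 10000 random lists as grey bars. The medians of 9 lists lay above their bar, 3 below and 12 within it.

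The machinery of DNA and RNA methylation was expressed at moderate levels. The 24 genes of cytosine DNA methylation and RNA-directed silencing had a median of 4.45 FPKM and a median rank of 52.3, within the range of random lists. AGO4, an Argonaute of RNA-directed DNA methylation, was highest at 17.9 ± 0.572 FPKM, NRPD2 (AT3G23780, NRPD2A in the table), a shared subunit of RNA polymerases IV and V, had 14.7 ± 0.698, and SHH1, with the largest SD, 4.28 ± 0.506. DRM1 was lowest, listed at 0 in libraries 1 and 3 and at 0.0307 in library 2. The 19 candidates for N6-adenine methylation had a median of 7.59 FPKM and a median rank of 62.8, also within that range. Against nuclear genes with a mean of at least 1 FPKM, the cytosine list had a median rank of 27.8, below the range of random lists, and the adenine list 43.6, within it; the members below 1 FPKM, 3 of 24 and 2 of 19, rank low there by construction. The 21 members of the cytosine list at that level had a median rank of 30.5, near the lower end of the range (29.5), and the 17 of the adenine list 44.2. On average over members, the difference of the cytosine list from the adenine list was -0.61 ± 0.02 in log2(FPKM + 1), in each of the 3 libraries (exact permutation p = 0.25).

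Among the cytosine methyltransferases, the maintenance enzyme MET1 had 6.36 ± 0.168 FPKM. The log2 difference from MET1 was -0.32 for CMT2 (SE 0.060), -0.39 for DRM2 (SE 0.058) and 0.17 for CMT3 (SE 0.055), each with the same sign in 3 of 3 libraries, with limma adjusted p-values of 0.000614, 0.000132 and 0.0120. The call on CMT3 was lost without replicate 1 and without replicate 3, where the difference was 0.15 and 0.16. Among the DNA demethylases, ROS1 (AT2G36490, DML1 in the table) had 11.6 ± 0.737 FPKM. DML2, at 3.46 FPKM, differed from it by -1.50 (SE 0.104), with a limma adjusted p of 3.3e-45, and of 8.8e-07 where the variances of both genes were used. DME, at 10.2 ± 0.474, differed from ROS1 by -0.16 (SE 0.089), which did not pass the test (limma adjusted p = 0.0696). Within libraries the difference had an SD of 0.025, and DME was higher in 0 of 3. The SE is moderated over the ratios of all genes to ROS1 and so holds noise of ROS1 that this pair does not show. The failed call therefore does not mean that the sign varied. DML3, at 0.655 ± 0.0301 FPKM, was below the filter and not tested.

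Among the 19 adenine methylation candidates, MTA (AT4G10760; TAIR10.1 chromosome 4, 6619817 to 6623381, minus strand, 7 exons), the catalytic subunit of the mRNA N6-adenosine methyltransferase, had 8.48 ± 0.257 FPKM. Its partner MTB (AT4G09980, named EMB1691 in the gene table) differed from it by -0.46 (SE 0.055), and the MT-A70 family gene AT1G19340 (TAIR10.1 chromosome 1, 6684467 to 6687116, plus strand, 8 exons), entered in the list as METTL4-like, by -1.58 (SE 0.082), with limma adjusted p-values of 5.9e-05 and 1.6e-07. AT1G19340 had 2.18 ± 0.193 FPKM. The subunits FIP37 and VIR (AT3G05680, named EMB2016 in the table) had 7.72 ± 0.0975 and 11.1 ± 0.193 FPKM. Of the AlkB-type dioxygenases, the gene entered as ALKBH10B (AT4G02940) was the most abundant, at 10.1 ± 0.561 FPKM. Those entered as ALKBH9B (AT2G17970), ALKBH1A (AT1G11780) and ALKBH9C (AT4G36090), and ALKBH2, differed from it by -0.92, -1.01, -1.34 and -2.005 on the log2 scale, all with limma adjusted p-values of at most 1.4e-07. ALKBH9C had the largest SD of the list, at 3.43 ± 0.681 FPKM. ALKBH10A (AT2G48080), at 0.352 ± 0.0678, was not tested, and ALKBH9A (AT1G48980) was listed at 0 in all 3 libraries. The YTH proteins bind N6-methyladenosine in RNA. ECT2 had 146 ± 2.82 FPKM, the highest of the 19, and ECT3 had 42.4 ± 2.17. The log2 difference from ECT2 was -1.76 for ECT3 (SE 0.041), -3.28 for ECT4 (SE 0.052) and -3.53 for ECT1 (SE 0.045), and all 3 differences had limma adjusted p-values of at most 7.8e-10. In all, 20 of the 21 family pairs tested passed 0.05, adjusted over the list alone. Each test of a family shares the noise of its reference gene, so the very small p-values say little beyond the direction.

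**Figure D3:**
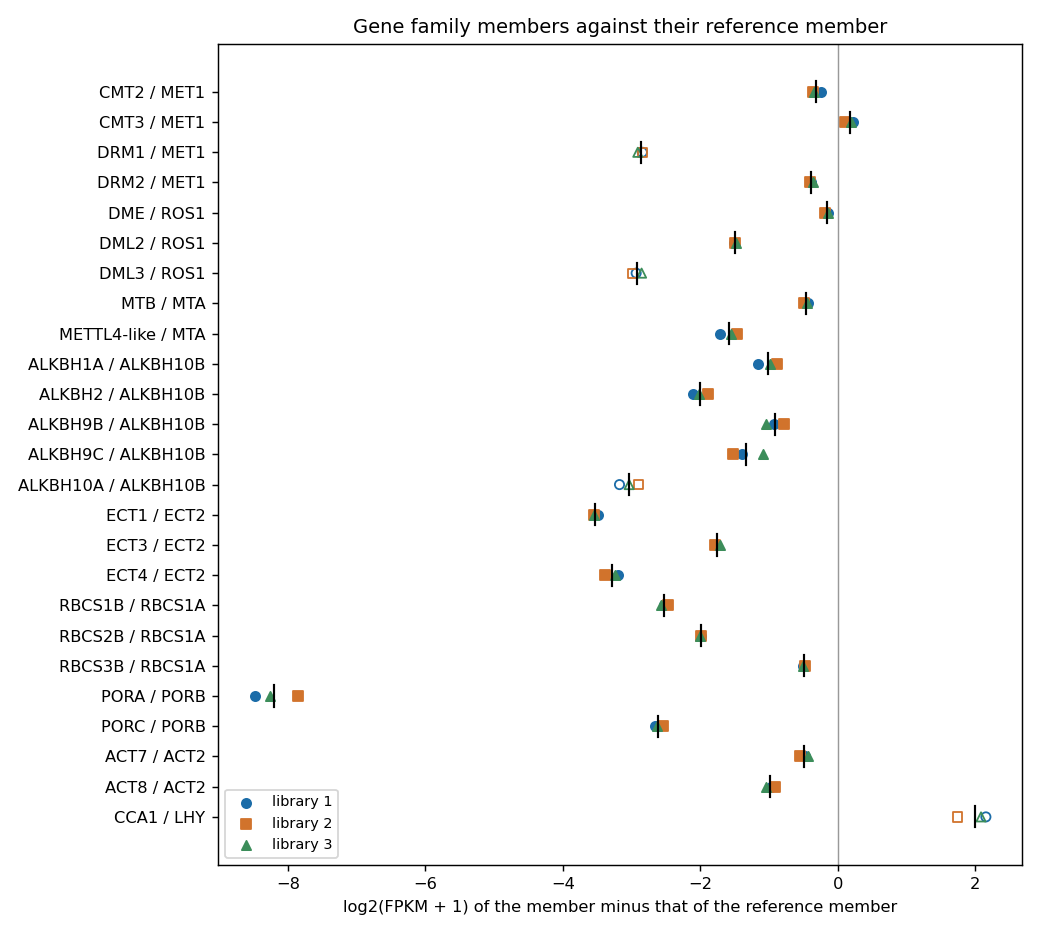
Difference in log2(FPKM + 1) between each family member and its reference member, with 1 symbol per library and a black bar for the mean; open symbols mark pairs below the filter, which were not tested, and ALKBH9A, listed at 0, is not drawn. PORA lay furthest below its reference, at -8.20, and CMT3 was the 1 tested member above its reference.

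Clock genes with an evening peak were more abundant than those with a morning peak. The 8 evening genes had a median of 33.5 FPKM and a median rank of 88.0, above the central 95% of random lists. GI had 59.5 ± 0.803 FPKM and LUX (AT3G46640, PCL1 in the table), a subunit of the evening complex, 53.9 ± 1.82, while PRR3 was lowest at 7.04 ± 0.589 and ELF4 varied most, at 14.1 ± 1.72. The 8 morning genes had a median of 10.3 FPKM and a median rank of 67.8, within that range. RVE4 (AT5G02840, LCL1 in the table) and PRR7 led them with 62.5 ± 1.56 and 26.9 ± 0.410 FPKM. LHY was lowest at 0.815 ± 0.162, and its partner CCA1, with the largest SD, had 6.28 ± 1.17. LHY was below the filter, so this pair was not tested. The difference of the morning list from the evening list was -1.23 ± 0.12 in mean log2(FPKM + 1), in each of the 3 libraries (exact permutation p = 0.25). The labels used here give no hour of harvest.

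Marker lists of roots, epidermis, vascular tissue and shoot meristem lay within the range of random lists, with at least 1 FPKM in 10 of 20, 14 of 15, 10 of 11 and 3 of 9 genes. The 20 root markers had a median of 1.26 FPKM and a median rank of 35.9. The root beta-glucosidase PYK10 reached 1009 ± 52.9 FPKM, the phosphate transporter PHT1;1 8.28 ± 1.49, the iron transporter IRT1, with the largest SD, 1.96 ± 0.979, and the nitrate transporter NRT2.1 (AT1G08090) 0.0292 ± 0.00101. A second match covered 58.5% of the transcript of PHT1;1, so its share of reads is uncertain. The 15 markers of shoot epidermis, stomata and trichomes had a median of 4.37 FPKM and a median rank of 51.9. FDH (AT2G26250, KCS10 in the table) and PDF1, genes of the epidermis, had 132 ± 5.28 and 87.6 ± 4.24 FPKM, MUTE 0.555 ± 0.234, and EPF1, with the largest SD, 2.67 ± 1.25. The difference of root markers from these was -1.34 ± 0.09 in mean log2(FPKM + 1) (exact permutation p = 0.25). The 11 vascular genes had a median of 8.11 FPKM and a median rank of 64.3. The sugar transporters SWEET11 and SUC2 had 116 ± 6.79 and 68.2 ± 2.77 FPKM, and VND7 0.255 ± 0.0424, while IRX1, with the largest SD, had 5.28 ± 0.525. The 9 shoot meristem genes had a median of 0.429 FPKM and a median rank of 28.3. CLV1 had 31.9 ± 0.599 and KNAT1 5.29 ± 0.546 FPKM, CUC1, with the largest SD, 0.429 ± 0.211, and WUS and CLV3 were listed at 0. With members and background both limited to a mean of at least 1 FPKM, all 4 lists stayed within that range. With only the background so limited, root markers and shoot meristem genes fell below it, where members below 1 FPKM rank low by construction.

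Floral, seed and pollen lists lay below the central 95% of random lists. The 12 genes of flowering and floral identity had a median of 0.197 FPKM and a median rank of 24.05. SOC1 (AT2G45660, AGL20 in the table) had 12.3 ± 0.470 FPKM and the floral repressor FLC 8.94 ± 0.324, whereas AP1 had 0.0489 ± 0.05004 and PI, with the largest SD, 1.12 ± 0.480. The 15 seed storage and embryo genes had a median of 0.0851 FPKM and a median rank of 21.01. OLEO2, an oleosin, had 2.40 ± 0.527 FPKM, EM6 (AT2G40170, GEA6 in the table), with the largest SD, 1.45 ± 0.790, and LEC1 was listed at 0. Light reaction genes exceeded this list by 10.46 ± 0.07 in mean log2(FPKM + 1), a value that the pseudocount of 1 holds down. The 8 pollen and sperm genes had a median of 0.0358 FPKM and a median rank of 18.1. ANX1 and BUPS1 (AT4G39110) had 2.199 ± 0.213 and 2.101 ± 0.125 FPKM, GEX2, with the largest SD, 0.718 ± 0.159, and VGD1 was listed at 0. With members and background both limited to a mean of at least 1 FPKM, the 4 floral genes left (median rank 45.2) and the 2 pollen genes left (11.3) lay within the range of random lists.

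Genes that respond fast to touch, wounding and cold were abundant, and so were those of abscisic acid and dehydration. The 16 touch, wound and cold genes had a median of 17.8 FPKM and a median rank of 79.2, above the central 95% of random lists. TCH4, a cell wall enzyme, had 209 ± 10.47 FPKM and TCH3, a calmodulin-like protein, 148 ± 8.00. JAZ7 had the largest SD, at 4.51 ± 1.82, and JAZ8 was lowest, listed at 0 in libraries 2 and 3 and at 0.548 in library 1. Against a background of nuclear genes with a mean of at least 1 FPKM this list had a median rank of 68.5 and no longer stood above random lists, but its 15 members at that level did, at 78.5. The 12 genes of abscisic acid and dehydration had a median of 33.8 FPKM and a median rank of 89.9. KIN2 had 1110 ± 37.5 FPKM, COR47 253 ± 8.14, ABI5 1.01 ± 0.196, and LTI30, with the largest SD, 9.90 ± 1.4. KIN1 had 2.23 ± 0.335, and second copies at 90% identity or more covered 17.37% of its transcript and 39.1% of that of KIN2. The other response lists lay within the range of random lists among all nuclear protein-coding genes, and with members and background both limited to a mean of at least 1 FPKM, 8 heat shock genes (median rank 20.5) and 6 flavonoid genes (13.7) fell below it. With only the background so limited, the salicylic acid defence list fell below it as well, as did these lists, where members below 1 FPKM rank low by construction. The 10 heat shock genes had a median of 2.75 FPKM and a median rank of 44.6, with HSP90.1 at 13.1 ± 1.26, HSFA7A at 5.58 ± 1.31, HSP21 at 0.264 ± 0.193 and HSP17.6II, with the largest SD, at 1.302 ± 0.955. The 13 genes of salicylic acid defence had a median of 1.52 FPKM and a median rank of 37.7, with WRKY70 at 22.6 ± 0.874, NPR1 at 13.4 ± 0.494, PAD3, with the largest SD, at 1.63 ± 0.932, and PR1 at 0 in libraries 1 and 2 and 0.0856 in library 3. The touch, wound and cold list exceeded the defence list by 2.38 ± 0.03 in mean log2(FPKM + 1) (exact permutation p = 0.25). The 12 flavonoid and anthocyanin genes had a median of 0.960 FPKM and a median rank of 33.2, with chalcone synthase TT4 at 8.98 ± 2.23, TT5 at 4.64 ± 0.183, PAP1, with the largest SD on the log2 scale, at 1.28 ± 0.552, and PAP2 (AT1G66390, MYB90 in the table) listed at 0. Of the 8 non-coding RNAs listed, 3 were in the files, with a median rank of 22.8. They were AT4 (AT5G03545), at 11.4 ± 1.73 FPKM, APOLO (AT2G34655), at 0.140 ± 0.121, and IPS1, listed at 0.

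Chloroplast-encoded transcripts made up most of the summed FPKM. They took 61.7%, 65.0% and 62.2% in libraries 1, 2 and 3 (63.0% ± 1.80, SD, n = 3), and mitochondria-encoded transcripts 1.38% ± 0.12. The highest chloroplast gene, ATCG00700, held 44.5% ± 1.096 of the total, with 892612 ± 38960 FPKM, and ATCG00630 followed with 73499 ± 5608. Without ATCG00700 the chloroplast share was 33.4%. The highest mitochondrial genes, ATMG01080 and ATMG00160, had 5302 ± 281 and 1975 ± 177 FPKM. Organelle genes are given by identifier, since the gene table used here pairs none of these identifiers with a symbol. No transcript length was read for them either, although the annotation gives coordinates of organelle genes such as atp9. Whether their values belong to the short transcripts whose FPKM is unstable was therefore not checked, and the shares are of FPKM, not of RNA amount. Nuclear genes together held 30.01% ± 0.699 of the summed FPKM. Transcripts without a locus held 7.24%, 4.14% and 5.55% of it in libraries 1, 2 and 3, so part of the difference in the other shares between libraries comes from them.

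The 3 libraries were close to each other across genes. Pearson's r of log2(FPKM + 1) was between 0.9951 and 0.9954 and Spearman's rho between 0.9902 and 0.9904 for the 3 pairs, across genes, which are not independent replicates. The SD of log2(FPKM + 1) over libraries had a median of 0.0859 among the 17868 genes with a mean of at least 1 FPKM. Of these, 117 (0.655%) differed by more than 1 on the log2 scale between their highest and lowest library. The number was 77, 56 and 48 without replicate 1, 2 and 3, and 306 with a pseudocount of 0.1, which widens the spread of low genes. With the pseudocount of 1, 20 of the 8451 genes with a mean of at least 10 FPKM differed by that much. Of the 10 most variable genes at that level, 4 were listed at 0 in at least 1 library: AT2G05803, AT5G66053, AT5G23411 and AT1G07901. AT2G05803 had 185 FPKM in library 2 and was listed at 0 in libraries 1 and 3. TOM7-2, a small subunit of the mitochondrial import complex, had 17.2, 3.91 and 10.7 FPKM in libraries 1, 2 and 3, and AT2G04050, a MATE efflux family gene, had 26.2, 13.0 and 42.0. The others were AT5G40180, AT2G35736, AT4G08555 and AT2G43018, with SDs of 0.93, 0.86, 0.81 and 0.71 on the log2 scale.

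Some gene lists shifted together between libraries. Light reaction genes were higher in library 1, by a median of 0.13 (log2) over the other libraries with 38 of 39 members above 0, and in library 3 their median deviation was -0.11. Matched random lists ranged from -0.004 to 0.077 in library 1 and from -0.088 to 0.032 in library 3, so 0 is not the baseline for such abundant genes. Cytosolic ribosomal protein genes in library 1 had 13 of 14 members above 0 and lay inside their range. Cytosolic ribosomal protein genes had a median deviation of -0.22 in library 2, with 0 of 14 members above 0, and of 0.15 in library 3, with 13 of 14. Other shifts outside the central 99% of expression-matched random lists were those of root markers in library 2 (-0.16), of shoot epidermis, stomata and trichomes in library 3 (-0.13), of touch, wound and cold genes in library 1 (-0.10) and of 6 flavonoid genes in library 2 (-0.25). These are 8 of 63 combinations of list and library, where random lists of unrelated genes give 0.63. Genes of 1 list can move together under ordinary noise between libraries, and the deviations of the 3 libraries depend on each other, so 0.63 is not a null value for these lists. Without replicate 1, 2 and 3 the number was 2, 4 and 6. With 1 library left out, the deviations of the remaining libraries mirror each other, so each shift is counted in both. These numbers are also out of fewer combinations, and do not compare directly with 8 of 63. The shifts of light reaction genes in library 1 and of ribosomal protein genes in library 2 kept their call under every alternative run, at 0.08 and -0.18 without replicate 3. Each library is centred on its median and these genes are abundant, so size factors, the pseudocount and the filter can change little here. Only the runs that left out a replicate could test these shifts closely. The other 6 lost their call under at least 1: without replicate 1, light reaction genes in library 3 (-0.07), root markers (-0.10), epidermis (-0.10) and flavonoid genes (-0.27); without replicate 2, ribosomal protein genes in library 3 (0.07, against 0.24 without replicate 1), epidermis (-0.11) and touch genes (-0.06); and without replicate 3, touch genes (-0.09) and flavonoid genes (-0.03).

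**Figure D4:**
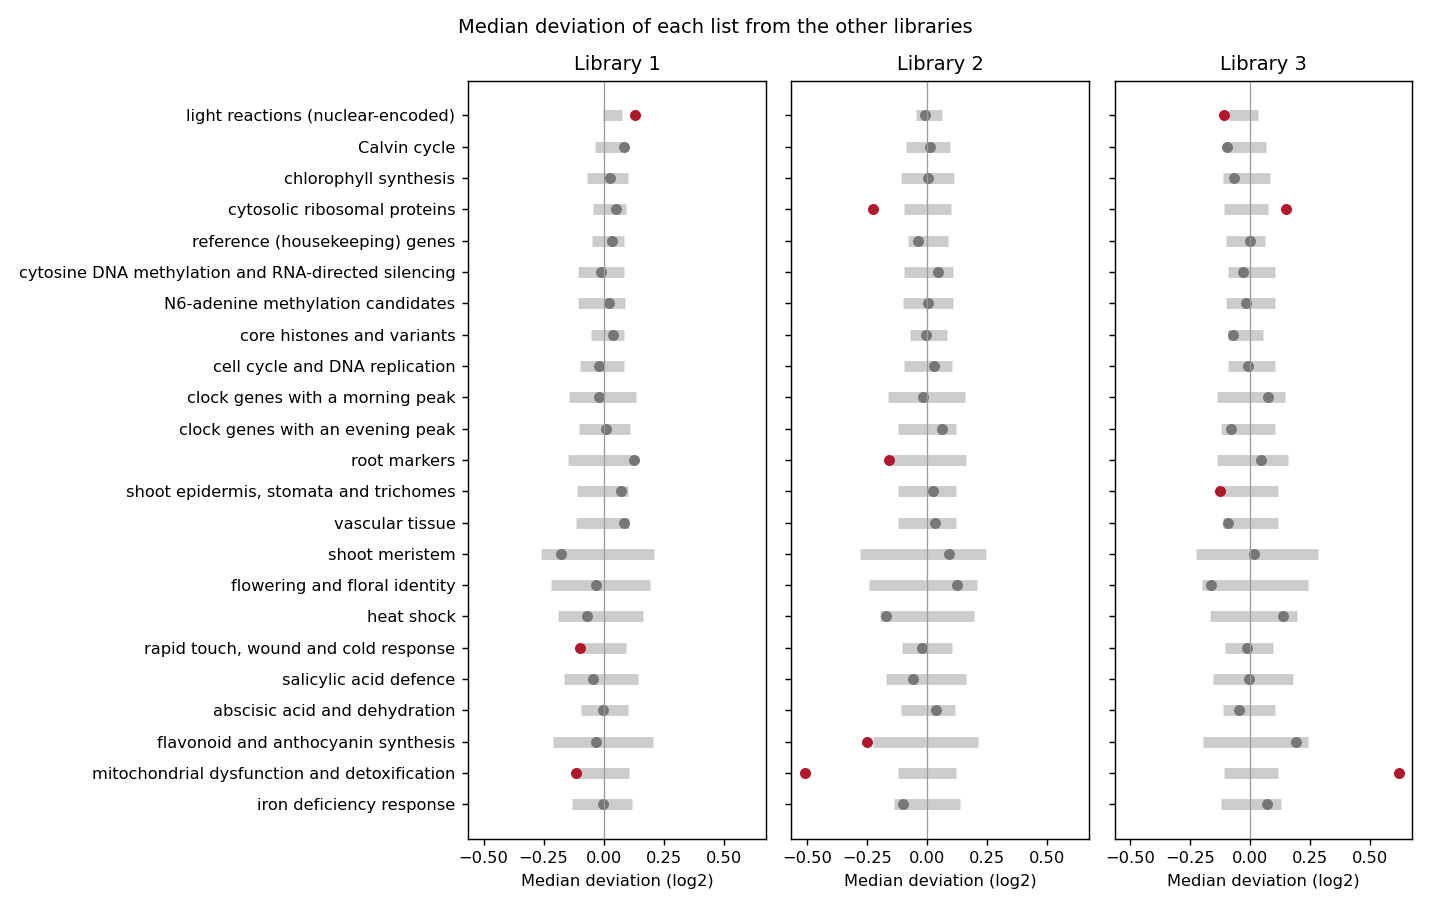
Median deviation (log2) of each gene list in each library from the mean of the other libraries, with the central 99% of 10000 expression-matched random lists as grey bars and medians outside it in red. The last pair of lists was assembled after the most variable genes had been seen; the detoxification list lay at 0.62 in library 3 and at -0.51 in library 2, where it was -0.23 without replicate 3.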

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

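Of the tests in this part, those on gene length, on snoRNA genes, on counting noise and on roots in library 2 were chosen after the result was seen, and the list of detoxification genes was assembled after the most variable genes had been seen. The removal of 1 gene from that list, given below, was also decided after its result was seen.

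Transcripts that the comparisons do not use carried signal. Of 835 transcripts without a TAIR locus, 407 had at least 1 FPKM in every library. The highest, TCONS_00007068, had a mean of 99638 FPKM (132821, 71559 and 94535 in libraries 1, 2 and 3), which is 4.95% ± 1.43 of the summed FPKM. Without coordinates for these identifiers in the files, no explanation was tested.

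Genes with short transcripts stood out among those that differed between libraries. Of 42 nuclear genes with 1 transcript of under 300 bases and a mean of at least 1 FPKM, 27 (64.3%) differed by more than 1 on the log2 scale, against 75 of 12444 longer ones (0.603%), a ratio of 106.7. The unit itself fits this, since 1 fragment may be worth a very high FPKM where the effective length is near 0, and 21 of the 27 were listed at 0 in at least 1 library. Such a gene can pass the mean filter only through a library where it was high, so the filter itself may raise the ratio. Reads shared with another locus were argued against: 3 of the 27, and 1 of 8 searched among the 10 most variable genes, had a second copy at 90% identity over 80% of the transcript (2 of the 10 had no transcript sequence). The length test was chosen after the pattern was seen, and no biological explanation was tested.

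Abundant nuclear genes outside the photosynthesis lists had technical candidates. Of the 20 most abundant nuclear genes, 1, AT2G07671, matched an organelle genome, so reads of organelle transcripts assigned to nuclear copies of organelle DNA may account for its 7385 FPKM. Another 1, AT2G35750, had a small structured RNA gene inside its exon on the same strand, so that its 18681 FPKM may come from snoRNA rather than from the annotated protein-coding transcript. For AT2G31141 and AT2G45180 neither explanation applies, and their levels stay without one. No biological explanation was tested.

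Detoxification and mitochondrial stress genes varied together. In 15 such genes with a mean of at least 1 FPKM, none of them among the 50 most variable genes with a mean of at least 10 FPKM, the median deviation was 0.6195 in library 3, with 15 of 15 members above 0, and -0.51 in library 2, with 0 of 15. The value in library 2 was -0.23 without replicate 3 and -0.71 without replicate 1. Of the 18 genes of the list, 3 had a mean below 1 FPKM and were left out, and AT12CYS-2 (AT5G09570) among them ran the other way, with 0.703, 0.832 and 0.484 FPKM in libraries 1, 2 and 3. The random lists draw unrelated genes, so they do not show how far related genes move together by chance. The list first held OM66 (AT3G50930, BCS1 in the gene table), which is among those 50 and was therefore taken out as the test had been written; with it the values over 16 genes were 0.61 and -0.48. Of the 15, only AOX1A and OPR1 have the mean of 10 FPKM that this ranking required, and others, such as DTX1 with an SD of 0.75 on the log2 scale, vary as much as genes in it. The list also holds relatives of genes in that ranking. DTX1 and DTX4 (AT2G04070) are MATE efflux family genes like AT2G04050, and CYP81D8 is named in 1 subfamily with CYP81D11. A second match covered 24.4% of the transcript of AT2G04050, so shared reads cannot be excluded. Counting noise was argued against, since the 12 list members with 1 transcript were all higher in library 3 than in library 2, by a median of 5.725 times their counting SD. This covers counting error of estimated fragments only, not duplicates or library preparation. The same measure on the most variable genes (13.42) is not used, because these were picked for their differences. A different share of roots was argued against as the whole cause of the rise in library 3, where root markers deviated by a median of 0.0463 (SD of the 10 members 0.24), inside the range of random lists. Lists of the shoot were lower there, as a changed share of organs would have it. Shoot epidermis deviated by -0.13 and light reactions by -0.11, both below the range. Calvin cycle genes (0 of 17 members above 0) deviated by -0.096, inside their range of -0.107 to 0.067. Vascular genes, which mark no single organ, were also lower but inside the range (0 of 10 members above 0). A changed share of organs as part of the cause stays open. For library 2 a different share of roots stays open as well: root markers deviated there by -0.1572, below the central 99% and in the same direction as the list, though less far. Without replicate 3 they deviated by -0.28, further than the list (-0.23), but they lost the call without replicate 1, with a pseudocount of 0.1 and without a filter. Other lists moved the same way in libraries 2 and 3. Cytosolic ribosomal protein genes deviated by -0.22 and 0.15, both outside the central 99%. Flavonoid genes deviated by -0.25, outside it, and 0.19, inside it, and heat shock genes by -0.17 and 0.14, both inside it. The shift was thus not particular to detoxification genes. A stress response that differed between the plants of these libraries may account for the shift of the detoxification genes, as a hypothesis. A difference in handling or harvest between libraries stays open, because the labels used here name no batch.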

How the results depend on the processing

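Variances of both genes in the family comparison, leaving out ATCG00700, the minimum length for genes that differ, the same filter for list members and background, and the added gene lists were chosen after seeing the data. No paired analysis was possible because the series holds 1 group, so no groups share replicate numbers. The number of genes detected (17369) stayed within 1.5 times under every alternative, from 17364 with size factors to 20386 at a minimum of 0.1 FPKM. The lowest Pearson's r was 0.9951 to 0.9954 when 1 replicate was left out and 0.9905 with a pseudocount of 0.1, and the median SD was 0.066 to 0.072 and 0.097; fewer libraries and a smaller pseudocount change these by construction. Genes that differ between libraries numbered 48 to 77 with 1 replicate left out and 306 with a pseudocount of 0.1, which widens the spread of low genes, but 161 without a filter, 110 with size factors and 89 for transcripts of at least 300 bases. The chloroplast share was 33.4% and the mitochondrial share 2.48% without ATCG00700, and otherwise both moved by less than the SD over libraries. The number of lists that stand apart was 12 in each run but 18 against nuclear genes with a mean of at least 1 FPKM, where members below 1 FPKM rank low by construction; with members under the same filter it was 12 again, but floral and pollen lists lost their call and heat shock and flavonoid lists gained one. All 7 list contrasts kept their sign under every alternative; with 3 libraries none can pass a threshold. Family pairs passing 0.05 numbered 19 or 20 of those tested, and 24 without a filter, where more pairs are tested. DME against ROS1 passed under none of 7 alternatives (adjusted p from 0.0520 to 0.287), and CMT3 against MET1 had adjusted p-values from 0.0110 to 0.0633. PORA could not be tested without replicate 2. Deviations of lists outside the range numbered 2 to 6 with 1 replicate left out, where each shift is counted in both remaining libraries, and 7 or 8 otherwise. Of the 8 with all libraries, 2 kept their call throughout, both of abundant genes for which only leaving out a replicate could change much. The other 6 lost it under at least 1 alternative, among them root markers with a pseudocount of 0.1 and without a filter, and flavonoid genes without a filter. The detoxification list in library 1 turned from -0.12 to 0.23 without replicate 3, since library 3 then leaves the mean it is set against, was -0.455 without replicate 2, and lost its call with size factors (-0.11) and with a pseudocount of 0.1 (-0.13). In libraries 2 and 3 that list kept its call throughout, but in library 2 it was -0.23 without replicate 3 and -0.71 without replicate 1, against -0.51 with all libraries. Without replicate 3, the 0.23 in library 1 and the -0.23 in library 2 are 1 difference seen from either side. Fragment numbers per gene are estimates, since whole reads were not recovered.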

Other observations

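The detoxification list was assembled, and the genes below were chosen, after the most variable genes had been seen; the test on iron genes was written before its result was seen. Of the 50 most variable nuclear protein-coding genes with a mean of at least 10 FPKM, 29 were both highest in library 3 and lowest in library 2. They include UGT74E2, a glycosyltransferase gene, with 20.8, 14.0 and 37.4 FPKM in libraries 1, 2 and 3, the multidrug transporter genes ABCB4 (14.4, 10.4 and 22.3) and ABCC3 (34.7, 27.8 and 55.6), and the cytochrome P450 gene CYP81D11 (17.5, 13.0 and 24.9). The 29 also include genes outside detoxification, such as the fibrillarin gene FIB2 (11.5, 8.51 and 14.9) and NAP57 (25.3, 18.4 and 30.5). In the detoxification list itself, AOX1A, the alternative oxidase, had 41.6, 37.98 and 54.5 FPKM, DTX1, an efflux carrier, 5.95, 3.99 and 12.8, and GSTU24, a glutathione transferase, 5.83, 3.53 and 8.27. The metallothionein gene MT1A was high in library 1, with 1851, 1184 and 1049 FPKM, but its transcript has 138 bases, in the length class whose FPKM was unstable.

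In genes with several transcripts, 1 form usually led. Of 2770 nuclear protein-coding genes with at least 2 listed transcripts and a mean of at least 10 FPKM, 2631 (94.98%) had the same leading transcript in all 3 libraries, and in 1534 (55.4%) it held at least 90% of the gene's FPKM.

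AT1G47400 and AT1G47395, annotated as uncharacterized proteins, were lowest in library 2, with 7.45 and 12.4 FPKM there against 11.5 and 24.2 in library 1 and 15.6 and 21.7 in library 3. This is not particular to them, since 36 of the 50 most variable nuclear protein-coding genes were lowest in library 2. An iron deficiency response that differed between libraries was tested as a hypothesis with 10 other iron deficiency genes with a mean of at least 1 FPKM. Their median deviation in library 2 was -0.1012, with 2 of 10 members above 0, inside the central 99% of random lists but at the 2.12 percentile of them. The bound set beforehand for this hypothesis (-0.14) was thus not reached. A median inside the range had been set beforehand as the outcome if the hypothesis were wrong, and that outcome was met. However, the list leaves out the genes that showed the pattern and its deviation has their sign, at a low percentile. The test therefore does not decide, and the hypothesis stays open.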
